A study of Escherichia coli K-12 with 4 samples.

How the data were processed

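Ribosome profiling (sequencing of the mRNA stretches that ribosomes shield from nuclease) was available for 4 libraries of Escherichia coli K-12 strain MG86, an MG1655 derivative in which the promoter of mgtA is replaced by the lacUV5 promoter. Cells were grown in M63 glucose minimal medium with 20 or 50 µM MgSO4 to late exponential phase, and each concentration had 2 libraries. Per the labels' protocols, ribosomes were halted with chloramphenicol, lysates were digested with micrococcal nuclease (MNase), and footprints were size selected after a sucrose cushion. No matched RNA-seq was used here, so a change in footprints can come from the mRNA level, from translation, or from both.

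The count table holds the deposited counts, whole reads per feature without normalization, for 4465 features. The submitters' processing notes list FastQC 0.11.9, cutadapt 3.7, Trimmomatic 0.38, Bowtie2 2.4.2, featureCounts from Subread 2.0.1 and edgeR 3.32.1. The settings, genome build, annotation, strand setting and treatment of reads with several matches are not given in the sources used here. Reads of features that overlap on the genome, and of near-identical copies such as the rRNA genes, tufA with tufB or argF with argI, may therefore be split or lost, and such features are uncertain. MNase cuts with a sequence preference, which affects positions within a gene more than sums over a gene.

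The authors also deposited a table of their own edgeR comparison, with a log2 fold change, a mean log2 CPM, a p-value, an adjusted p-value and a call for each feature. Its log2 fold changes run 50 over 20 µM, as a check against the counts showed, and are printed here with that direction named. An edgeR exact test on the unfiltered deposited counts, with no normalization factors and a dispersion fixed at 0.04 (a biological coefficient of variation of 0.2), returned the authors' log2 fold changes with a largest difference of 6.66e-15. Its log10 p-values had a median ratio of 1 to those of the authors' deposited table, taken only over features with a low p-value there. The p-values in the authors' deposited table thus follow an assumed spread, not the spread between these libraries. Features with an adjusted p under 0.05 and an absolute log2 fold change above 1 carry the authors' calls.

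The columns of the count table name the concentration and a number from 1 to 4, with libraries 1 and 3 at 20 µM and libraries 2 and 4 at 50 µM. These numbers are not the replicate numbers of the sample titles, so columns were assigned to groups only. Libraries held 3664062 reads (20 µM, library 1), 3118265 (20 µM, library 3), 3631101 (50 µM, library 2) and 2929755 (50 µM, library 4). Only 779140 to 1051293 of them lay in protein-coding genes. A count of 0 in a library allows up to 0.746 to 1.04 CPM from 3 counts, and this limit and the intervals below cover counting error only. Libraries of one group were far apart, with a chi-square per degree of freedom of 156 for libraries 1 and 3 and 61.7 for libraries 2 and 4, so none is a second copy of another. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

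The main test was edgeR's quasi-likelihood test (version 4.0.16 in R 4.3.3, default settings, trimmed-mean-of-M-values factors, TMM) with the concentration as the only factor. The default expression filter (minimum count 10, minimum total 15) left 2853 features. Two-sided p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05, and log2 fold changes run 20 over 50 µM. The fit had 2 residual and 3.58 prior degrees of freedom. Standard errors (SE) are the unshrunken coefficient over the square root of the F statistic. CPM values use TMM-scaled library sizes and are given as mean ± SD with n = 2. Ratios between single libraries use log2 of scaled counts after adding 0.5 counts. In a design of 2 against 2, an exact permutation test of a single value cannot give a two-sided p below 0.333, so no such p is reported.

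Before the data were examined, 34 gene lists, the rule for named genes and the alternatives were fixed. Of the lists, 33 had at least 3 tested members and were tested with camera on the edgeR object (limma 3.58.1), with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 33 lists. The genes always named were mgtA, mgtL, mgtS, corA, phoP, phoQ and lacZ. Per direction, up to 12 called genes with the largest fold changes and no overlap between the groups' libraries were to be named, rRNA and tRNA excepted, and with fewer than 5 such genes the list was filled to 10 by the smallest unadjusted p. Within a described list, up to 4 members past the threshold were to be named, or the 2 with the highest mean CPM where none passed. Once 0 features had passed over all genes, this threshold was read as adjusted over the list alone, a choice made after seeing the data. Other genes in the text were chosen after their values were seen. Gene symbols are those of the count table. For RNA class and neighbouring genes, 4430 features were matched by symbol and 34 by a synonym to a RefSeq gene table of strain MG1655 (assembly ASM584v2), and 1 was unmatched. Coordinates are not printed, because the build of the count table is not named.

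Alternatives were other normalizations, filters, tools (DESeq2 1.42.0, edgeR's exact and likelihood ratio tests, limma-voom), dispersion settings, feature sets, thresholds, other set tests, and leaving out each library. One alternative was added after the data were seen. Across 1642 features other than rRNA and tRNA with over 200 reads in total, the log2 difference of library 1 from 3 correlated with that of library 2 from 4 (Pearson r = 0.77 across features, which are not independent replicates). Each of these pairs, libraries 1 with 2 and 3 with 4, holds one library of each concentration, and a fit with the pair as a block lowered the common dispersion from 0.111 to 0.0266. Libraries 1 and 2 correlated at r = 0.93, libraries 3 and 4 at r = 0.97, libraries 1 and 3 at r = 0.89 and libraries 2 and 4 at r = 0.90.

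The tests were run on simulated data made from the means, library sizes and dispersions of the 2853 tested features, in 5 runs with 200 changed features each. With differences between library pairs simulated, the main test recovered 0% of the 2-fold, 39.4% of the 4-fold, 83.6% of the 8-fold and 92.4% of the 16-fold changes. The block on library pairs recovered 64.6%, 99.2%, 100% and 100% of these, and 3.83% of its calls were false. The simulated pair differences and dispersions were those of the block fit itself. These rates therefore leave out any error from choosing the pairing after seeing the data. Without pair differences the main test recovered 8.98%, 69.5%, 98.0% and 98.8% with 6.16% of its calls false, and the block 10.6%, 69.1%, 96.8% and 98.8% with 7.17% false. In a simulation with 1 shifted list, camera found that list and called 0 of the others. This simulation drew each feature independently, without inter-gene correlation or pair differences, so it cannot show whether the preset correlation was adequate.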

Results

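Ribosome footprints were compared between Escherichia coli grown with 20 µM and with 50 µM MgSO4, of which the protocol names the latter as the high magnesium condition. The title of the series concerns MgtL, a leader peptide encoded upstream of mgtA, the gene of a P-type ATPase that imports magnesium. The strain carries lacUV5 in place of the mgtA promoter, so the native promoter of mgtA was absent under both conditions. Each concentration had 2 libraries, and the 4 libraries held 2929755 to 3664062 reads. Protein-coding genes took 24.0% to 33.7% of the reads, rRNA 24.6% to 42.5% and tRNA 29.4% to 42.2%. The rRNA share averaged 33.5% ± 12.7 (SD, n = 2) at 20 µM and 27.4% ± 3.48 (SD, n = 2) at 50 µM, and it was largest in library 1 (20 µM). Of 4465 features, 4252 had at least 1 read and 2853 were tested.

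Footprints on mgtA were 5.40-fold higher at 20 µM, with 1134 ± 521 CPM at 20 µM and 210 ± 11.9 CPM at 50 µM (mean ± SD, n = 2 each). Footprints on mgtL were also higher at 20 µM, with 290 ± 111 CPM there and 96.5 ± 17.0 CPM at 50 µM (mean ± SD, n = 2 each). Both genes were higher in both 20 µM libraries than in either 50 µM library. The log2 fold changes of 20 over 50 µM were 2.43 (SE 0.42) for mgtA and 1.59 (SE 0.37) for mgtL. Neither passed edgeR's quasi-likelihood test after adjustment over all features, at adjusted p = 0.57 for mgtA and 0.64 for mgtL. Adjusted over the list of magnesium transport genes alone, both passed, at 0.0043 and 0.0088. With the library pair as a block, an alternative chosen after seeing the data, the edgeR adjusted p of mgtA was 0.0077 and that of mgtL 0.029, and over all alternatives that of mgtA ran from 1.6e-05 to 0.999. In the authors' deposited table the log2 fold changes of 50 over 20 µM were -2.26 for mgtA and -1.43 for mgtL, with adjusted p-values of 7.24e-11 and 0.000299.

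The ratio of mgtA to mgtL reads, which library scaling leaves as it is, was 4.08 in library 1 (exact binomial 95% interval 3.83 to 4.35) and 3.63 in library 3 (3.34 to 3.96), both from 20 µM. At 50 µM it was 2.58 in library 2 (2.28 to 2.94) and 1.86 in library 4 (1.62 to 2.14). The means were 3.85 ± 0.316 at 20 µM and 2.22 ± 0.513 at 50 µM (SD, n = 2 each), so mgtA differed between the concentrations by more than mgtL did in these libraries. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, and no other test of the ratio was run. lacZ, the first gene of the operon whose promoter lacUV5 derives from, had 0 reads in all 4 libraries, which allows up to 0.746 to 1.04 CPM. It lies in a run of 29 neighbouring features with 5 reads in total, so this limit holds only if the strain carries the gene, which was not tested by sequence. All 4 genes of the lac operon list stayed below the expression filter, and lacA had 1 read in library 1 and 1 in library 2.

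Genes of the PhoPQ regulon, which the magnesium sensor kinase PhoQ and the regulator PhoP control, were higher at 20 µM as a group. The list includes mgtA and its leader peptide gene mgtL, although the native mgtA promoter was absent in this strain. The rise of mgtA and mgtL can therefore not be read as control by PhoP at that promoter. Of 16 tested members, 14 rose and 0 fell when adjusted over the list alone, and 0 passed when adjusted over all genes, or 12 with the block on library pairs. All 16 were higher in both 20 µM libraries than in either 50 µM library, an order that chance gives to 16.7% of features per direction. Of all tested features 14.9% had this order, and list members are not independent of each other. The median log2 fold change was 2.35, with 2.88 for library 1 over 2 and 1.54 for library 3 over 4. camera called the list at an adjusted p of 4.0e-37 with the preset correlation, and the call was lost at adjusted p = 0.75 with an estimated correlation. With 2 residual degrees of freedom, an estimated correlation left little power to pass over 33 lists, for this list and those below. Adjusted over the list alone, mgtS, a small membrane protein that stabilizes MgtA, rose by 4.51 on the log2 scale (SE 0.81), from 99.4 ± 25.6 CPM at 50 µM to 3716 CPM in library 1 and 813 CPM in library 3. It overlaps mgtT, which is in no list and had a log2 fold change of 4.51 (SE 0.87), so reads of these genes may be shared. mgrB, a small protein that restrains PhoQ, rose 8.54-fold to 111 ± 72.7 CPM (SD, n = 2), with 163 CPM in library 1 and 59.7 CPM in library 3, and slyB, an outer membrane lipoprotein, rose 5.27-fold to 3038 ± 946 CPM (SD, n = 2). The regulator gene phoP rose by 2.32 (SE 0.43) and the kinase gene phoQ by 1.60 (SE 0.38) on the log2 scale, although phoQ reached only 15.4 ± 5.34 CPM at 20 µM (SD, n = 2) and overlaps phoP. ybjG, an undecaprenyl pyrophosphate phosphatase gene, rose by 3.15 (SE 0.61). Without library 1 (20 µM) the log2 fold changes of mgtS, mgtT, mgrB and ybjG were 3.04, 3.54, 2.21 and 2.17, and without library 3 (20 µM) they were 5.24, 5.12, 3.66 and 3.74. Without library 4 (50 µM) that of mgtT was 5.84. The members that did not pass were ompT, an outer membrane protease gene, with a log2 fold change of 0.81 (SE 0.34), and treR, the trehalose repressor gene, with 0.47 (SE 0.46). For treR the log2 ratio was 0.77 for library 1 over 2 and 0.08 for library 3 over 4.

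**Figure D1:**
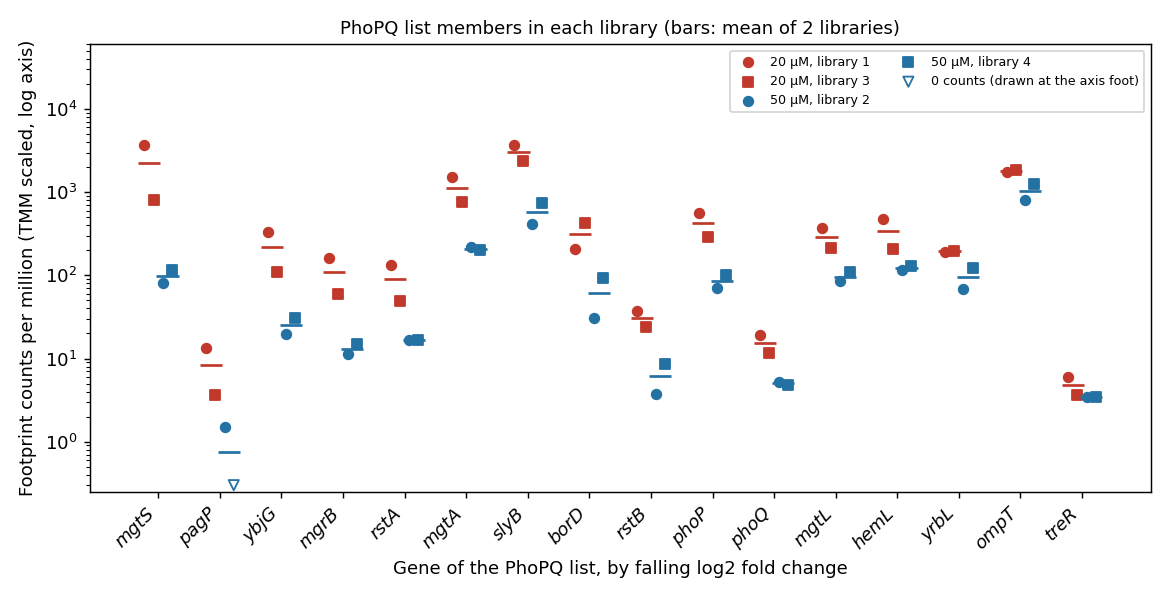
Footprint CPM (TMM scaled, log axis) of the 16 tested PhoPQ list members in each of the 4 libraries, with red for 20 µM, blue for 50 µM, a bar for the mean of 2 libraries and an open triangle for a count of 0. Each gene lies higher in both 20 µM libraries than in either 50 µM library, with log2 fold changes from 4.51 for mgtS to 0.47 for treR.

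Among 7 tested magnesium transport genes, 4 rose and 1 fell when adjusted over the list alone, and 0 passed when adjusted over all genes, or the same 5 with the block on library pairs. Those that rose were mgtA, mgtS, mgtL and corA, the last encoding the main constitutive magnesium channel. corA rose 2.50-fold, to 237 ± 23.3 CPM at 20 µM from 94.7 ± 12.2 CPM at 50 µM (SD, n = 2 each). ybeX, also named corC and linked to magnesium efflux, fell by 2.62 on the log2 scale (SE 0.39), with 6.82 ± 0.310 CPM at 20 µM and 42.1 ± 17.5 CPM at 50 µM (SD, n = 2 each). The other members were yfjD, with a log2 fold change of -0.82 (SE 0.33), and pitA, with 0.44 (SE 0.25). camera called the list at an adjusted p of 0.0031, and the call was lost at adjusted p = 0.83 with an estimated correlation, at 0.16 on ranks and at 0.076 without library 2 (50 µM). Of these genes, mgtA, mgtL and mgtS are also on the PhoPQ list.

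Across all 2853 features, edgeR's quasi-likelihood test called 0 higher and 0 lower at 20 µM, the smallest adjusted p being 0.57. At an unadjusted p under 0.05 there were 73 higher and 86 lower, where chance gives 143 in total. DESeq2 called 15 higher and 1 lower, edgeR's exact test 11 and 4, its likelihood ratio test 13 and 6, and limma-voom 0 and 0. The fit with a block on library pairs, chosen after seeing the data, called 41 higher and 21 lower. Without library 3 (20 µM) edgeR called 12 higher and 0 lower, and without library 4 (50 µM) 5 higher and 3 lower. In 425 features (14.9%) both 20 µM libraries lay above both 50 µM libraries and in 581 (20.4%) below, against 16.7% by chance per direction. The features of smallest p on the higher side were mgtA, mlaD, mgtS, mgrB, slyB, phoP, hisD, mgtT, ybjG and ynfB. mlaD, part of a transporter that keeps lipid asymmetry in the outer membrane, had 51.5 ± 4.92 CPM at 20 µM and 18.9 ± 0.342 CPM at 50 µM (SD, n = 2 each). On the lower side they were ybeX, macA, uvrC, gsiA, ybeZ, lhr, mutM, yciY, yfeO and gsiD. Log2 fold changes there were -2.22 (SE 0.41) for macA, of a macrolide exporter, -1.41 (SE 0.28) for uvrC, of nucleotide excision repair, -1.84 (SE 0.39) for gsiA and -1.37 (SE 0.38) for gsiD, of a glutathione importer, and -1.53 (SE 0.32) for ybeZ, a neighbour of ybeX. For lhr, mutM, yciY and yfeO they were -2.04 (SE 0.45), -2.15 (SE 0.51), -1.03 (SE 0.25) and -1.86 (SE 0.51). At 20 µM the means of macA, gsiD, lhr, mutM and yfeO were 2.48, 3.57, 2.01, 1.86 and 1.24 CPM. The folds of these genes rest on few reads. A count of 0 allows up to 0.943 CPM in library 1 and 0.918 CPM in library 3.

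On the list of histidine and aromatic amino acid genes 6 of 26 members rose and 0 fell when adjusted over the list alone, all of them in the histidine operon, and adjusted over all genes 0 passed, or the same 6 with the block on library pairs. hisD rose 3.46-fold, with 329 ± 17.2 CPM at 20 µM and 95.2 ± 33.0 CPM at 50 µM (SD, n = 2 each), hisB rose 2.45-fold, hisA 2.55-fold and hisC 2.50-fold. The remaining risers were hisH, 2.28-fold, and hisG, 2.82-fold. hisF, hisI and the aromatic amino acid genes did not pass. camera called the list higher at an adjusted p of 0.0019, with a median log2 fold change of 0.17 (0.08 with upper-quartile factors). The call was lost at adjusted p = 0.83 with an estimated correlation and at 0.16 on ranks. Without library 3 (20 µM) the median was -0.27 at an adjusted p of 0.34, and without library 2 (50 µM) it was -0.17 at 0.62, while without library 1 (20 µM) or library 4 (50 µM) it was 0.50 or 0.65.

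camera called the lists of sulfur amino acid genes and of heat shock genes lower at 20 µM with the preset correlation and not with an estimated one. On the methionine and cysteine list 25 of 30 members had negative log2 fold changes, with a median of -0.75, but 0 passed by edgeR when adjusted over the list alone and 0 when adjusted over all genes. Of these, 14 lay lower in both 20 µM libraries, an order that 20.4% of all tested features had. List members come from the same libraries and are not independent. cysK, the gene of the main cysteine synthase, had 1000 ± 18.6 CPM at 20 µM and 1644 ± 812 CPM at 50 µM, and metE, a methionine synthase gene, 709 ± 104 and 997 ± 5.06 CPM (SD, n = 2 each). camera called the list at an adjusted p of 1.3e-06, lost at adjusted p = 0.83 with an estimated correlation and at 0.073 without library 1 (20 µM), where 12 of 30 were positive and the median was -0.45. Without library 2 (50 µM) the median was -0.49 and the log2 fold change of cysK went from -0.72 to -0.09, and without library 4 (50 µM) 12 of 30 were positive. On the heat shock list 18 of 19 members had negative log2 fold changes, with a median of -0.79, and 0 passed by edgeR when adjusted over the list alone or over all genes. The chaperone gene dnaK had 622 ± 161 CPM at 20 µM and 1275 ± 763 CPM at 50 µM, and groL 827 ± 397 and 1064 ± 536 CPM (SD, n = 2 each). camera called this list at an adjusted p of 4.7e-05, lost at adjusted p = 0.94 with an estimated correlation, at 0.068 without library 3 (20 µM) and at 0.27 without library 2 (50 µM). The median was then -0.45 with 3 of 19 positive and -0.24 with 7 of 19 positive. Without library 2 (50 µM) the log2 fold change of dnaK went from -1.04 to -0.24, and that of groL went from -0.36 to 0.28, and to 0.07 without library 3 (20 µM). With the block on library pairs, 4 members of the sulfur list (cysD, cysC, cysM and cysJ) and 2 heat shock genes (hslV and ibpA) were called lower.

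**Figure D2:**
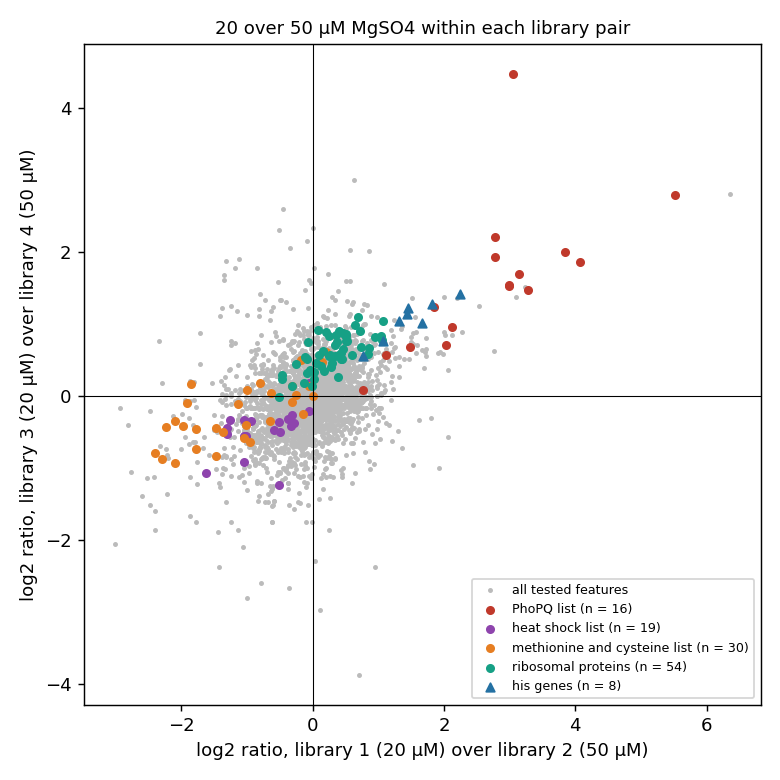
Log2 ratios of 20 over 50 µM for library 1 over 2 (horizontal axis) and library 3 over 4 (vertical axis), with each tested feature as a grey point and 4 gene lists and the his genes in colour. PhoPQ list members lie at positive values on both axes, with medians of 2.88 and 1.54, and heat shock genes have medians of -0.59 and -0.42.

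Ribosomal protein genes had a median log2 fold change of 0.50, and 50 of 54 were positive, though for most the libraries of the groups overlapped. By edgeR 0 passed when adjusted over the list alone or over all genes, and 4 over all genes with the block on library pairs. rplN had 2755 ± 804 CPM at 20 µM and 1453 ± 149 CPM at 50 µM, and rpmF 1759 ± 382 and 1420 ± 390 CPM (SD, n = 2 each). camera called the list at an adjusted p of 6.8e-07, which was lost at adjusted p = 0.98 with an estimated correlation. Without library 3 (20 µM) 25 of 54 were positive, with a median of -0.05 and an adjusted p of 0.96, and without library 2 (50 µM) the median was 0.21 at 0.19. Without library 1 (20 µM) or library 4 (50 µM) it was 0.89 or 0.92. The rRNA share was 24.6% in library 3 and 29.9% in library 2.

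camera also called the porin and outer membrane list higher (adjusted p = 0.0019, 13 members, median 0.54), lost at adjusted p = 0.83 with an estimated correlation, at 0.071 without library 3 (20 µM) and at 0.27 without library 2 (50 µM). Its median was 0.14 without library 3, 0.22 without library 2, 0.92 without library 1 (20 µM) and 1.19 without library 4 (50 µM). Its most abundant members were lpp, with a log2 fold change of 0.40 (SE 0.42), or -0.00 without library 3, and ompA, with 1.00 (SE 0.58), or 0.41 without library 2 and 2.06 without library 4. Stable noncoding RNA (26 members, mostly rRNA) was called higher at an adjusted p of 0.00036 with a median of 0.41, lost at adjusted p = 0.75 with an estimated correlation and at 0.081 with at least 50 counts in each group mean (18 members), and its near-identical rRNA copies cannot be counted as separate genes. Its most abundant members, rrlG and rrlD, had log2 ratios of 1.09 and 1.05 for library 1 over 2, but 0.05 each for library 3 over 4. The rRNA share of library 3 (20 µM, 24.6%) lay below those of libraries 2 and 4 (50 µM, 29.9% and 25.0%). Without library 1 (20 µM) the list's median was 0.43, with 20 of 26 positive. Respiratory chain and ATP synthase genes (32 members, median 0.24) were called higher at 0.023, lost at adjusted p = 0.86 with an estimated correlation, at 0.19 with at least 50 counts in each group mean (27 members, median 0.14), at 0.26 without library 1 (20 µM), where the median was 0.11, and at 0.22 without library 2 (50 µM); without library 4 (50 µM) the median was 0.39. With upper-quartile factors it was 0.14 with 19 of 32 positive, and with total counts 0.14 with 18 of 32 positive. atpA had a log2 fold change of 0.47 (SE 0.29) and atpD 0.32 (SE 0.27). The curli and biofilm list (5 members, median -0.77) was called lower at 0.021, lost at adjusted p = 0.83 with an estimated correlation, at 0.22 without library 3 (20 µM), at 0.093 without library 2 (50 µM), at 0.063 with no filter (12 members), at 0.12 on ranks and at 0.12 with the block on library pairs, with a median of -1.20 without library 1 (20 µM), and with -1.06 (SE 0.44) for csgD and 0.42 (SE 0.34) for csgA. In each of these 4 lists 0 members passed by edgeR when adjusted over the list alone or over all genes, and with the block on library pairs 1 porin list member, ompX, passed over all genes.

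The other 23 lists were not called by camera. Their adjusted p-values were 0.081 for phosphate starvation, 0.11 for glycolysis, 0.13 for arginine, 0.21 for BasRS lipid A modification, 0.31 for the TCA cycle, 0.32 for ribosome hibernation and for polyamines, 0.33 for translation factors and 0.35 for potassium transport. They were 0.41 for iron uptake and for nucleotide biosynthesis, 0.48 for the SOS response, and 0.57 for aminoacyl-tRNA synthetases, branched-chain amino acids and cold shock. For general stress under RpoS the value was 0.72, for flagella 0.79, for leader peptides 0.87, for envelope stress 0.89, for colanic acid 0.98, for ribosome assembly and for acid resistance 0.99, and for zinc, manganese and nickel 0.99. Once a library is left out, the library pairs are not balanced over the concentrations. A difference between pairs then enters the fold changes, so the calls that follow cannot be read as effects of the concentration. Without library 1 (20 µM) camera called RpoS (0.0067), acid resistance (0.013) and phosphate starvation (0.017) lower, and polyamines (0.027), arginine (2.8e-20), nucleotide biosynthesis (0.0058) and cold shock (0.013) higher. Without library 3 (20 µM) RpoS (0.0018), acid resistance (0.029), phosphate starvation (3.0e-13), iron uptake (0.017) and the TCA cycle (0.0027) were called higher, and arginine (1.1e-07) and branched-chain amino acids (0.0034) lower. Without library 2 (50 µM) phosphate starvation (5.6e-07), iron uptake (0.0010) and the TCA cycle (0.015) were called higher and branched-chain amino acids (7.0e-05) lower, and without library 4 (50 µM) arginine (0.0072) and branched-chain amino acids (0.028) higher. Phosphate starvation and arginine were called higher with total counts (both 0.020), and arginine (0.043) and glycolysis (0.022) on ranks. Adjusted over the list alone, pmrD, which links PhoPQ to lipid A modification, rose by 2.17 on the log2 scale (SE 0.47), or 2.89 without library 4 (50 µM), and was the only member past the threshold in these lists. pstS, a phosphate binding protein gene, had a log2 fold change of 1.88 (SE 0.95), with 0.20 without library 1 (20 µM), 2.66 without library 3 (20 µM), 3.09 without library 2 (50 µM) and 1.29 without library 4 (50 µM). The arginine gene argG had 1.08 (SE 0.86), with -0.53 for library 1 over 2 and 1.58 for library 3 over 4, and with 1.89 without library 1 (20 µM) and -0.89 without library 3 (20 µM). With the block on library pairs camera called phosphate starvation (adjusted p = 0.00063) and glycolysis (0.049), and both were at 0.87 once the correlation was also estimated. In that fit edgeR passed 2 phosphate genes (pstS and phoB), pmrD, the leader peptide gene mgtL, and on the lower side ivbL and ilvA.

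In the authors' deposited table, a total of 53 features carry a call of lower at 50 µM, that is higher at 20 µM, and 60 a call of higher at 50 µM. Of these 113, 111 were tested here, all 111 with the same direction, and 77 had an unadjusted p under 0.05 by edgeR's quasi-likelihood test. The libraries of the groups did not overlap in 89 of the 111, but the authors' deposited table was made from the same libraries. The log2 fold changes of the authors' deposited table, sign turned, correlated with those computed here at r = 0.997 across features, which are not independent replicates. The block on library pairs called 52 of the 111.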

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

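The block on library pairs was chosen only after the data were seen, and the other alternatives were planned. For the titles' replicate numbers no paired analysis was possible because the columns do not carry them, and the block pairs libraries by column number instead. The counts of 0 higher and 0 lower features became 15 and 1 with DESeq2, 11 and 4 with edgeR's exact test, 13 and 6 with its likelihood ratio test, and 41 and 21 with the block on library pairs; leaving out each library gave 0 to 12 higher and 0 to 3 lower. All 16 DESeq2 calls were also block calls. mgtA kept its direction under every alternative, at log2 fold changes of 2.47 with DESeq2, 2.43 with edgeR's exact and likelihood ratio tests, 2.36 with the block and 1.88 to 2.85 leaving out each library. Of 74 genes with alternatives 5 changed sign, each without a call and only with a library left out: groL to 0.28 without library 2 (50 µM) and 0.07 without library 3 (20 µM), lpp to -0.00, argG to -0.89 and argD to -1.26 without library 3 (20 µM), and phoB to -0.49 without library 1 (20 µM). With fixed inter-gene correlation the PhoPQ list was called leaving out each library (adjusted p 4.38e-50 to 1.32e-24), but its adjusted p was 0.755 with an estimated correlation, 0.718 with fry and 0.873 with block and estimated correlation. For magnesium transport these were 0.826, 0.834 and 0.873, with 0.164 on ranks and 4.66e-05 to 0.0758 leaving out each library. All 10 called lists lost the call with an estimated correlation and with fry. The fit left 2 residual degrees of freedom, so an estimated correlation left little power to pass over 33 lists. In that setting the PhoPQ list had an unadjusted camera p of 0.043. The losses with an estimated correlation therefore do not decide whether inter-gene correlation accounts for the calls. Some lists not called with all libraries turned direction with a call when one library was left out, RpoS at 0.0067 and phosphate starvation at 0.0172 without library 1 (20 µM), acid resistance at 0.0292 and arginine at 1.11e-07 without library 3 (20 µM), and branched-chain amino acids at 0.0276 without library 4 (50 µM). Leaving out each library gave 0.00184 to 0.367 for RpoS, 2.98e-13 to 0.685 for phosphate starvation, 0.0131 to 0.301 for acid resistance, 2.8e-20 to 0.451 for arginine and 7.0e-05 to 0.263 for branched-chain amino acids. With a library left out, the pairs are not balanced over the concentrations, so a difference between pairs enters the fold change. Whether this accounts for the turns was not tested. Upper-quartile factors and total counts moved the median log2 fold change of all features from -0.02 to -0.12 and -0.15. In simulated libraries with pair differences, 2-fold changes were not recovered by the group-only fit (0%), while the block recovered 64.6%. That simulation took its pair differences and dispersions from the block fit itself.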

Other observations

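All tests of explanations in this part were chosen only after the results were seen. Of some genes outside the named set, chosen after their values were seen, mlaF, mlaE, ybjX, lpxT and lnt passed edgeR's test with the block on library pairs. The lipid transport genes mlaF and mlaE, neighbours of mlaD, had log2 fold changes of 1.46 (SE 0.35) and 1.18 (SE 0.27) and adjusted p-values of 0.039 and 0.029 in that edgeR fit. ybjX, of unknown function, had 2.12 (SE 0.59), at 431 ± 9.20 CPM against 99.4 ± 76.5 CPM (SD, n = 2 each), with 1.49 without library 2 (50 µM) and 3.29 without library 4 (50 µM). lpxT, of lipid A phosphorylation, had 2.03 (SE 0.51), or 1.40 without library 1 (20 µM). Next to ybeX and ybeZ, lnt, of lipoprotein acylation, had -1.18 (SE 0.35), and ybeY, of rRNA maturation, which did not pass with the block (adjusted p = 0.084), had -1.42 (SE 0.49), or -0.61 without library 2 (50 µM). The glutathione importer genes gsiB and gsiC, beside gsiA and gsiD, had -1.64 (SE 0.48) and -1.74 (SE 0.63), and did not pass with the block (adjusted p = 0.062 and 0.14). They were at -0.87 and -0.83 without library 2 (50 µM), and gsiC at -2.34 without library 3 (20 µM).

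For the higher footprints of the PhoPQ list at 20 µM, unequal rRNA and tRNA shares and a difference between library pairs were considered. Unequal shares would move all protein-coding features of a library alike, but in unscaled counts the list's median lay 2.93 (library 1 over 2) and 1.56 (library 3 over 4) above that of the others on the log2 scale. A difference between pairs alone cancels from the fold change by design, since each pair holds a library of each concentration. Within pairs the smaller median of the list was 1.54, so neither explains the shift alone. Each ratio within a pair compares single libraries, so other differences between single libraries were not addressed. A response of the cells to magnesium stays a hypothesis, and footprints do not separate mRNA level from translation.

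Zinc-responsive genes split the libraries by pair: zinT, a periplasmic zinc protein gene, was 78.3-fold higher in library 1 than in library 3 and 134-fold higher in library 2 than in library 4, and for znuA, of the zinc importer, these folds were 31.7 and 51.8. The alternative ribosomal protein genes ykgM and ykgO were 47.0- and 94.8-fold higher in library 1 than 3, and rpmE, the counterpart of ykgM, was 6.99-fold higher in library 3 than 1, while rpmJ, that of ykgO, was 1.52-fold higher. In the opposite direction, copper efflux gene cusF was 38.4-fold and nickel importer gene nikA 23.2-fold higher in library 3 than in library 1. The split was not limited to metal genes. dcuB was 134-fold higher in library 3 than 1 and 58.6-fold higher in library 4 than 2. For the pyrimidine gene pyrB these folds were 29.1 and 9.59, and for fumB, of the TCA cycle list, 16.6 and 21.4. Depth or scaling is argued against by a median of unscaled counts over all features of at most 0.496 (log2), where the 6 zinc-responsive genes had 5.23 and 6.85. Libraries 1 and 3 shared one magnesium concentration and libraries 2 and 4 the other, so by design it cannot set them apart. Within pairs the medians of the 6 genes were -0.119 (library 1 over 2) and 0.596 (library 3 over 4), with ykgM at 2.60 in the latter. A batch shared by libraries 1 and 2, and another by 3 and 4, is a candidate explanation that stays open: the correlation of 0.738 across 1630 features repeats the one that prompted the pairing and so does not decide it, and the labels name no batch.

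A run of 29 neighbouring features around lacZ, from yahI to mhpE, held 5 reads in total, and 26 of them had 0 reads. In 10000 shuffles of the feature order 0% gave a run as long, the longest being 9, and the next longest real run was 7. Of the 29, 89.7% were at 0, against 42.4% of 441 other features with at most 2 reads (one-sided Fisher's exact p = 3.65e-07). The run was picked from these same counts, and neighbouring features are not independent. A silent segment would raise the share at 0 too, so this p cannot tell absence from silence. Absence of this segment from the strain may explain the run. The flanking features yahG, yahH, mhpT and yaiL had 5, 4, 7 and 490 reads, so the edges of the run are not sharp, and a segment that is present but silent stays open. No genome sequence was used here, so a strain difference could not be decided, and no other biological explanation was tested.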
